A study of Mus musculus with 8 samples.

How the data were processed

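Epithelial cells of the mouse small intestine were released with DTT and EDTA washes, stained for EPCAM and CD45, and sorted as CD45-negative, EPCAM-positive, Il25-RFP-positive tuft cells with or without Chat-GFP, per the labels' protocols. The cells went into SMARTer v4 lysis reagents, and libraries were made from the amplified cDNA with Nextera XT and read as single reads over 74 cycles, per the same source. By its general chemistry that kit primes on poly(A) tails. Such libraries do not mark strand and carry no molecular identifiers, so overlapping genes and PCR copies cannot be told apart and counting errors cover counting only. The animals were naïve, per the series' design text. The values are raw counts per gene symbol as deposited by the authors in 1 table. Whole numbers with unequal totals per column bear out that unit. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here.

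Samples were grouped by the cell population in the labels, 4 Chat-neg and 4 Chat-pos libraries. The labels do not say which animals the libraries came from, so p-values measure the spread between these libraries, which may in part be technical. All pairs of libraries in a group differed by more than counting noise. The table had 53806 rows, of which 36 had no gene name. These 36 held 88.4%, 74.8%, 67.8% and 71.2% of all counts in Chat-neg replicates 1 to 4 and 64.2%, 64.6%, 61.9% and 58.6% in Chat-pos replicates 1 to 4, and were kept out of library sizes and tests. Counts of 229 rows that shared 114 symbols were summed, which left 53655 symbols. Positions, exon lengths and GC content came from GENCODE M21 on GRCm38, which held 52744 of the symbols. Genes that share exons with another annotated gene, among those named Tnc, Zfp52, Gbp8, Mtmr11, Ttn, Smpd3, Ppp2r3a, Lrrc31, Tk1, COX1, Sh2d7, Il17rb, Rpl12, Eps8l3, Sema4a, Pdia6, Hspe1, Jun, Gapdh, Fdft1 and Hmgcs1, are uncertain, as are ribosomal protein genes, Defa genes, H2 genes and Gapdh, which have near-identical copies.

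Gene counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, a robust quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values are counts per 1e6 of TMM-scaled gene totals, and are given as mean ± SD over 4 libraries. The common biological coefficient of variation was 28.1%. Gene lists with at least 5 measured members were tested with limma 3.58.1, using camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 31 preset lists. Of these, 19 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.214; fry also passed 11 of the 19. The lists, 10 primary, 18 secondary and 8 of cell type markers, the design and the rule for named genes were fixed before the data were examined. The rule took Chat, Slc18a3, Il25, Epcam and Ptprc, the 12 genes with the largest rise and the 12 with the largest fall. Both sets of 12 came from called genes with a mean of at least 10 CPM over all libraries, non-overlapping groups and no predicted-model name. It added the 3 members of each list with the smallest p (2 in lists under 8 members). With the 2 most abundant members of each marker list, it gave 111 genes in all. Other genes named in the text were picked out after their values were seen.

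Depth sets the precision. In Chat-neg replicate 1, with 87642 counts in named genes, Chat rested on 9 counts, against 506 to 858 in the Chat-pos libraries. Reads on 1430 olfactory and vomeronasal receptor genes served as a measure of background, with Vmn2r26, a receptor known from tuft cells, left out. That the others are silent in these cells is assumed and was not tested, and any expression among them makes the background look higher. The reads were 357, 613, 450 and 371 in Chat-neg and 505, 402, 368 and 381 in Chat-pos, which is 4073, 782, 382 and 607 CPM against 287, 168, 168 and 149.9 CPM. Library measures were compared with exact two-sided permutation tests (scipy 1.17.1), 15 in number, of which 3 were added later. On simulated counts for the 8919 tested genes, edgeR recovered 7.46% of genes changed 1.5-fold, 25.4% of those changed 2-fold and 72.7% of those changed 4-fold. Of 79 calls 6 were false, and 0 of 40 unchanged lists passed camera. The simulated genes varied independently of each other. In the data the estimated correlation within lists ran from -0.053 (Notch pathway) to 0.946 (Paneth cell markers), with 0.649 for ribosomal proteins. The simulation therefore says nothing on false calls of camera in correlated lists.

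The alternatives were RLE, upper-quartile and total count scaling, no filter on low counts, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, thinning to the smallest library, a minimum fold of 1.5, and leaving out each library. After the data were seen, 5 more were added: thinning to the second smallest library without the shallowest, leaving out both Chat-pos libraries rich in Paneth cell transcripts, subtracting background reads by exon length from all libraries or from Chat-neg alone (the most that background can take from the difference), and an offset for exon length and GC content, which were known for 99.5% of tested genes.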

Results

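Tuft cells are rare chemosensory cells of the gut epithelium that release the cytokine IL-25, and a part of them also expresses choline acetyltransferase, the enzyme that makes acetylcholine. RNA was measured in tuft cells of the mouse small intestine that had been separated by flow cytometry from animals carrying a red reporter for Il25 and a green reporter for Chat. The cells without green signal (Chat-neg) and those with it (Chat-pos) gave 4 libraries each. Counts in named genes were 87642, 784036, 1176880 and 610756 in Chat-neg replicates 1 to 4, and 1757401, 2387464, 2190134 and 2541955 in Chat-pos replicates 1 to 4. The groups did not overlap in depth (exact two-sided permutation test, p = 0.0286, the smallest p that 4 against 4 libraries allow; adjusted p = 0.0536 over 15 library measures, and 0.0429 over the 12 measures computed first). The comparison asks how tuft cells with an active Chat reporter differ from tuft cells without it.

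Chat mRNA was higher in the Chat-pos gate, at 330 ± 34.1 CPM against 117 ± 22.5 CPM in Chat-neg (SD, n = 4 each), a log2 difference of 1.46 ± 0.21 (SE; adjusted p = 6.28e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Slc18a3, the vesicular acetylcholine transporter, stood at 13.5 ± 6.82 CPM in Chat-pos and 12.3 ± 9.13 CPM in Chat-neg and did not pass the test (log2 difference 0.53 ± 0.56, edgeR adjusted p = 0.653). Both genes lie on the minus strand of chromosome 14 in GRCm38, Chat at 32408203 to 32465989 and Slc18a3 at 32462438 to 32464850, inside the span of Chat. Il25, whose reporter defined both gates, was higher in Chat-pos, at 119 ± 22.1 CPM against 45.8 ± 28.4 CPM (log2 difference 1.12 ± 0.26, edgeR adjusted p = 0.00884). It lies on chromosome 14 at 54932695 to 54935837. Ptprc, which encodes the CD45 antigen used to exclude leukocytes, rose by 0.99 ± 0.20 on the log2 scale (561 ± 85.4 CPM against 279 ± 25.8 CPM, edgeR adjusted p = 0.00313). Epcam, the epithelial antigen of the sort, did not pass (0.38 ± 0.20, edgeR adjusted p = 0.289).

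**Figure D1:**
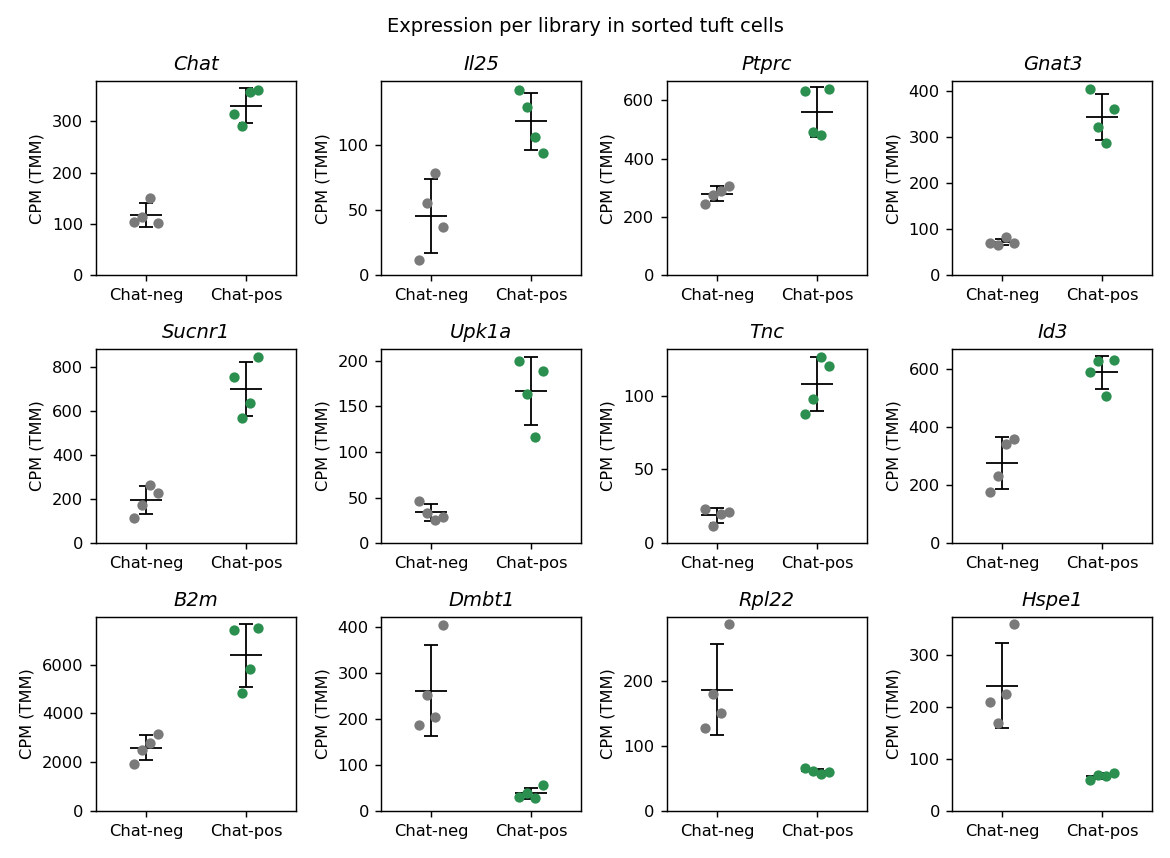
Normalised expression (CPM after TMM scaling, linear axes from 0) of 12 genes in the 4 Chat-neg and 4 Chat-pos libraries; points are libraries, and black marks are the group mean with its SD. Chat, Gnat3, Sucnr1, Upk1a, Tnc and B2m lie higher in all Chat-pos libraries, and Dmbt1, Rpl22 and Hspe1 lower.

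Over all 8919 genes tested, 323 were higher and 256 lower in Chat-pos (edgeR's quasi-likelihood test, adjusted p under 0.05), and 150 of the former and 156 of the latter by more than 2-fold. Gnat3, the taste G protein alpha subunit gustducin, rose from 72.0 ± 7.42 to 343 ± 50.6 CPM (log2 difference 2.24 ± 0.22, edgeR adjusted p = 1.68e-07), and Sucnr1, the succinate receptor, from 196 ± 64.8 to 704 ± 123 CPM (1.78 ± 0.23, edgeR adjusted p = 1.86e-05). Upk1a, a uroplakin, rose by 2.46 ± 0.25, Tnc, which encodes the matrix protein tenascin C, by 2.60 ± 0.28, and Fxyd2, a regulator of the sodium pump, by 3.01 ± 0.47 on the log2 scale. Crip2, Vamp5, Gbp8, Isg15, Mtmr11, Zfp52 and Hoxb7 completed the 12 genes with the largest rise, with log2 differences from 1.76 (Mtmr11) to 1.95 (Crip2). That ranking covers called genes with a mean of at least 10 CPM over all libraries and non-overlapping groups. Calhm3 (4.94) lay below that mean, and Hoxb9 (2.38) overlapped between the groups. Dmbt1, a secreted scavenger receptor of mucosal surfaces, fell from 261 ± 98.4 to 38.0 ± 12.6 CPM (-2.81 ± 0.26, edgeR adjusted p = 4.45e-07). Clca1, a product of goblet cells, was lower by -3.06 ± 0.55, Rbp7, a retinol-binding protein, by -2.96 ± 0.63, and Lrrc31 by -1.91 ± 0.37. Fgfbp1, Vapb, Snord13, Edn2, Cdca3, Smpd3 and Ppp2r3a had log2 differences from -2.53 (Fgfbp1) to -1.95 (Ppp2r3a). Snord13 is annotated as a snoRNA of 104 bp. It lost its call when background reads were subtracted from all libraries or from Chat-neg alone, and whether its reads are background was not tested. Ttn, the muscle protein titin, was lower by -3.16 ± 0.54, and its mean count per Chat-neg library was 17.

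Leaving out Chat-neg replicate 2 lowered the counts to 138 higher and 110 lower genes, and the lower count fell to 163, 124 and 141 without Chat-neg replicate 3, Chat-neg replicate 4 and Chat-pos replicate 3. The calls Zfp52, Hoxb7, Rbp7, Fgfbp1, Vapb, Snord13, Edn2, Cdca3, Smpd3 and Ppp2r3a were lost without at least 1 library. Vapb passed in 0 of the 8 fits, Hoxb7 and Snord13 in 3 and Zfp52 in 4. Fgfbp1 and Cdca3 lost theirs without Chat-neg replicate 4 and Smpd3 without Chat-neg replicate 2. With total count scaling the split was 225 higher and 380 lower, with the median of all genes at -0.14 on the log2 scale.

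Genes of tuft cell identity were higher in Chat-pos. Of 38 measured members, 17 rose and 1 fell, and 23 rose and 1 fell when adjusted over the list alone, with a median log2 difference of 0.59 (limma's camera, adjusted p = 1.12e-11, and adjusted p = 0.298 with an estimated correlation). Reep5 rose by 1.65 ± 0.22, Sh2d7 by 1.08 ± 0.20 and Il17rb, the IL-25 receptor subunit, by 0.96 ± 0.20. Among the members that did not pass were Dclk1, at 0.29 ± 0.21, Avil, at 0.17 ± 0.20, and Pou2f3, at 0.41 ± 0.23, which were picked out after their values were seen. Of the 38 members, 26 also stand in another list used here.

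The taste-type cascade had 7 members higher and 1 lower of 15 (9 and 1 adjusted over the list alone; camera, adjusted p = 8.46e-08, and adjusted p = 0.214 with an estimated correlation). Gnat3 and Sucnr1 rose, as did Calhm3, a channel subunit of taste cells, at 14.4 ± 5.25 CPM in Chat-pos against 0.401 ± 0.802 CPM in Chat-neg. Gng13, the G protein gamma subunit of the cascade, fell. Of the type 2 immune cytokines and receptors, 4 of 9 rose over all genes and adjusted over the list alone, among them Il25, Il17rb and Tslp, which encodes an alarmin cytokine (1.15 ± 0.25, edgeR adjusted p = 0.0051). Camera gave that list an adjusted p = 0.00682, and an adjusted p = 0.214 with an estimated correlation. Of 18 haematopoietic-type genes that tuft cells express, 5 rose (8 adjusted over the list alone), including Ptprc, Rac2 (0.96 ± 0.22) and Siglecf (0.88 ± 0.22), with a camera adjusted p = 0.000393 and an adjusted p = 0.397 with an estimated correlation. Without Chat-neg replicate 2, the members that rose were 8 in the identity list, 4 in the taste-type cascade and 1 in the haematopoietic list, and the last count was 3 without Chat-neg replicate 4, Chat-pos replicate 1 or Chat-pos replicate 3. No member of the taste-type cascade was lower in 7 of 8 fits that left out a library, all but the fit without Chat-pos replicate 1. Rac2 and Siglecf lost their calls without Chat-neg replicate 2.

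Interferon-response genes were higher in Chat-pos, with 10 of 35 rising and none falling, and 16 rising when adjusted over the list alone. The median log2 difference was 0.61 (camera, adjusted p = 1.42e-09, and adjusted p = 0.214 with an estimated correlation). Isg15, a ubiquitin-like modifier, rose by 1.77 ± 0.31, Bst2 by 1.17 ± 0.27 and Oas1a by 1.06 ± 0.24. In the antigen presentation list, B2m rose from 2597 ± 507 to 6389 ± 1295 CPM and H2-D1, a class I heavy chain, by 1.25 ± 0.21. They were 2 of the 3 members of 17 that rose (3 adjusted over the list alone; camera, adjusted p = 0.00115, and adjusted p = 0.214 with an estimated correlation), and the third, H2-K1 (0.67 ± 0.21, edgeR adjusted p = 0.0498), kept its call only without Chat-neg replicate 1. The interferon count was 1 without Chat-neg replicate 2, 5 without Chat-neg replicate 4, Chat-pos replicate 1 or Chat-pos replicate 3, and 6 with total count scaling. Bst2 and Oas1a lost their calls without Chat-neg replicate 2.

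Genes of cytoplasmic ribosomal proteins were lower in Chat-pos. Of 76 members, 52 fell and none rose (66 fell when adjusted over the list alone), 75 had a negative difference, and the median was -0.95 on the log2 scale (camera, adjusted p = 2.95e-39, and adjusted p = 0.232 with an estimated correlation). Rpl22 fell from 186 ± 70.4 to 60.6 ± 4.05 CPM (-1.67 ± 0.22, edgeR adjusted p = 2.3e-05), and Rpl12 (-1.70 ± 0.23) and Rpl38 (-1.46 ± 0.21) fell too. Nuclear-encoded genes of oxidative phosphorylation were lower in 16 of 77 cases and higher in none (24 lower and 1 higher adjusted over the list alone), with a median of -0.35 (camera, adjusted p = 7.49e-08, and adjusted p = 0.429 with an estimated correlation). Among them Ndufa4 (-1.27 ± 0.21), Ndufc1 (-1.26 ± 0.21) and Atp5k (-1.31 ± 0.23) fell, but fry did not pass the list (adjusted p = 0.111). Of 9 mitochondrially encoded transcripts, 2 rose (3 adjusted over the list alone), COX1 by 1.34 ± 0.22 and CYTB by 0.85 ± 0.21 (camera, adjusted p = 0.0489, and adjusted p = 0.429 with an estimated correlation). That list call was lost without Chat-neg replicate 2 or 4 or Chat-pos replicate 2 or 3. Mitochondrially encoded transcripts took 4.79 ± 0.373% of gene counts in Chat-neg and 7.59 ± 1.42% in Chat-pos (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0536 over 15 library measures). The share was 8.86% and 8.65% in Chat-pos replicates 2 and 3, which are rich in Paneth cell transcripts, and 5.85% and 7.02% in Chat-pos replicates 1 and 4. With the Paneth-rich libraries left out, 20 ribosomal protein genes and 1 oxidative phosphorylation gene fell, and both lists still passed camera (adjusted p = 6.52e-25 and 0.0135). Ribosomal protein genes took 1.44% and 1.28% of gene counts in the Paneth-rich libraries, 1.44% and 1.38% in the other Chat-pos libraries and 1.76% to 3.64% in Chat-neg. Without the Paneth-rich libraries the mitochondrially encoded list no longer passed (adjusted p = 0.15), with COX1 its 1 member to rise. That count was 4 without Chat-neg replicate 1 and 1 without Chat-neg replicate 2 or 4 or Chat-pos replicate 2. The ribosomal count was 34 without Chat-neg replicate 2 and 30 without Chat-neg replicate 4. The oxidative phosphorylation count was 28 without Chat-neg replicate 1, 6 without Chat-neg replicate 2, 5 without Chat-neg replicate 3, and 7 without Chat-neg replicate 4, Chat-pos replicate 2 or Chat-pos replicate 3. CYTB lost its call without Chat-neg replicate 2 or 4 or Chat-pos replicate 2.

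**Figure D2:**
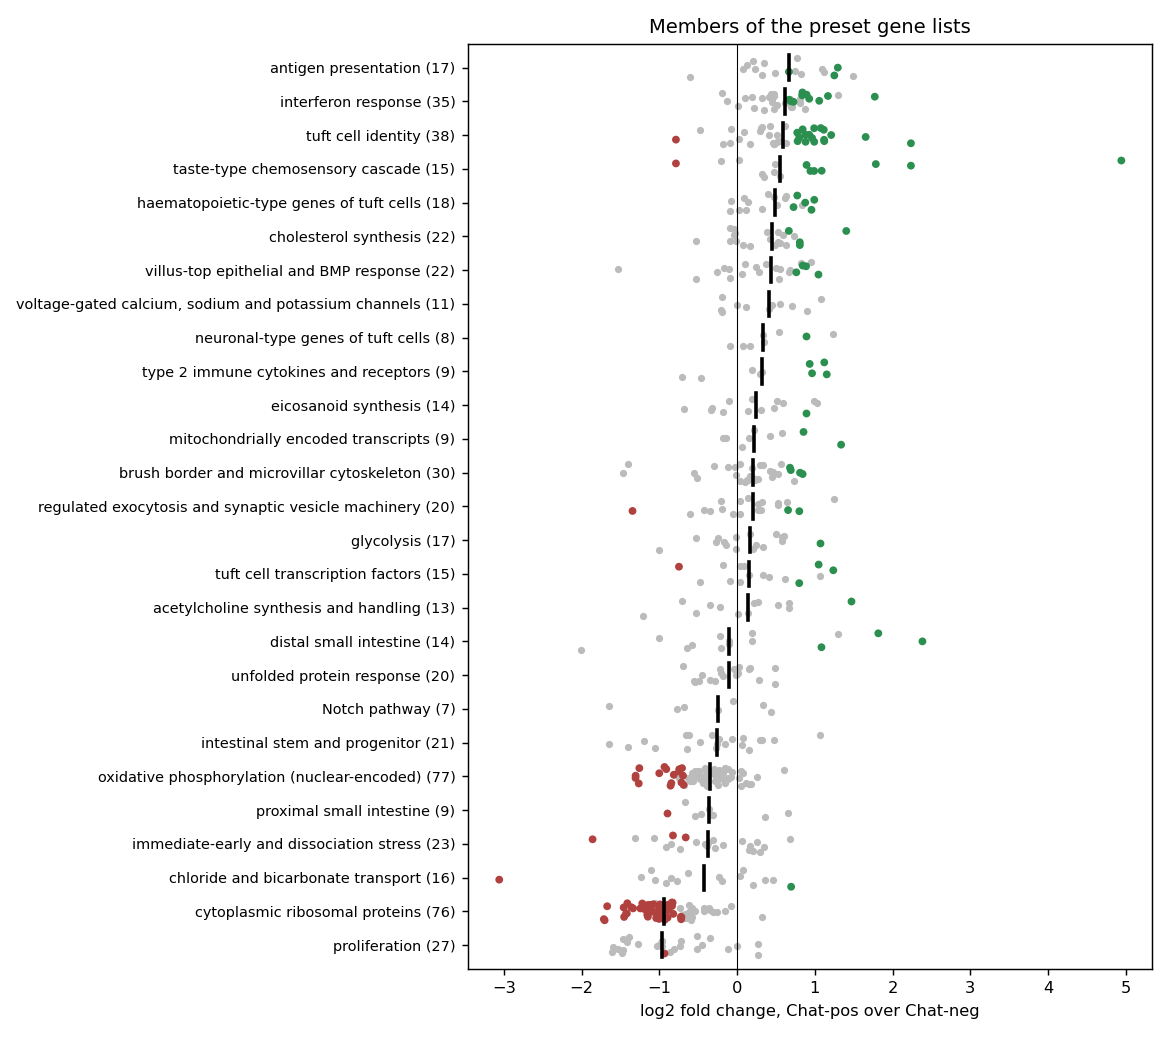
Log2 fold change (Chat-pos over Chat-neg) of each measured member of the preset gene lists, with the number of members in brackets; green and red points passed the edgeR test in the upward and downward direction, grey points did not, and black bars are list medians. Ribosomal protein genes centre on -0.95 and tuft cell identity genes on 0.59.

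Proliferation genes had a median of -0.96 on the log2 scale and 25 of 27 members below 0, yet the sole member to fall was Tubb5 (-0.94 ± 0.24; 1 also adjusted over the list alone). Mcm5 stood at -1.47 ± 0.52 and Tk1 at -1.47 ± 0.57 without passing. Camera gave an adjusted p = 0.000124, and an adjusted p = 0.429 with an estimated correlation; without Chat-neg replicate 4 the preset value was 0.0815. Tubb5 lost its call without Chat-neg replicate 2 or 4 or Chat-pos replicate 4, and 4 members fell without Chat-neg replicate 3. In the stem and progenitor list 0 of 21 members passed with edgeR over all genes or adjusted over the list alone, with Hes1 at -1.64 ± 0.49 and Cd44 at -1.19 ± 0.47 (camera, adjusted p = 0.205, and 0.029 without Chat-neg replicate 3). Among 22 genes of the villus top and BMP response 4 rose (7 adjusted over the list alone), including the BMP targets Id3 (1.05 ± 0.22), Id2 (0.84 ± 0.21) and Id1 (0.89 ± 0.23). Camera gave this list an adjusted p = 0.00243, and an adjusted p = 0.397 with an estimated correlation, and 2 of its genes rose without Chat-neg replicate 2. Id2 lost its call in that fit, and Id1 there and without Chat-pos replicate 1.

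Cholesterol synthesis genes rose in 4 of 22 cases (8 adjusted over the list alone), among them Fdft1, which encodes squalene synthase (1.40 ± 0.23), and Hmgcs1 (0.81 ± 0.20). Camera gave an adjusted p = 0.0013, and an adjusted p = 0.232 with an estimated correlation, and 1 gene rose without Chat-neg replicate 2 or 3, where Hmgcs1 lost its call, and 2 without Chat-pos replicate 1 or 4. In the list of acetylcholine synthesis and handling, Chat was the 1 member of 13 that rose (2 adjusted over the list alone, with Slc44a4 at 0.67 ± 0.22; camera, adjusted p = 0.397). Of 16 chloride and bicarbonate transport genes, Ano7 rose (0.69 ± 0.20) and Clca1 fell, also when adjusted over the list alone, while Slc9a3 stood at -1.24 ± 0.44 (camera, adjusted p = 0.146). That list passed without Chat-pos replicate 3 (adjusted p = 0.0314), without Chat-neg replicate 1, and with both Paneth-rich libraries left out (0.0384, with 2 members lower). Without Chat-pos replicate 4 the lower members were 4, and 2 without Chat-neg replicate 1 or Chat-pos replicate 1, 2 or 3. The call of Ano7 was lost in 5 of 8 fits that left out a library, Chat-neg replicates 2 to 4 and Chat-pos replicates 2 and 3. Eicosanoid synthesis genes had 1 of 14 members higher, Mgst3 (0.88 ± 0.22; 1 adjusted over the list alone; camera, adjusted p = 0.0979, and 0.0326 without Chat-neg replicate 3). Mgst3 lost its call without Chat-neg replicate 2 or Chat-pos replicate 4. In the exocytosis list Napa and Cadps2 rose and Rab3d fell of 20 members (3 and 1 adjusted over the list alone; camera, adjusted p = 0.146). Each of these 3 calls was lost in 6 of 8 fits that left out a library. Distal small-intestinal genes had 3 of 14 higher, Osr2 (1.08 ± 0.25), Hoxb7 and Hoxb9 (3 adjusted over the list alone), although the list's median was -0.11 and its mean 0.15 (camera, adjusted p = 0.405). Of 9 proximal genes Onecut2 fell (-0.90 ± 0.23; 1 adjusted over the list alone; camera, adjusted p = 0.146, and 0.044 without Chat-pos replicate 4). None of the 3 distal genes passed without Chat-neg replicate 3. Onecut2 lost its call without Chat-neg replicate 3 or 4 or Chat-pos replicate 4.

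Further lists passed camera only at the margin. Tuft cell transcription factors had 3 of 15 higher and 1 lower (4 and 1 adjusted over the list alone), with 1810046K07Rik at 1.05 ± 0.21 (camera, adjusted p = 0.0324, and adjusted p = 0.397 with an estimated correlation). Brush border genes had 4 of 30 higher (6 higher and 1 lower adjusted over the list alone), among them Espn and Eps8l3 (camera, adjusted p = 0.0489, and adjusted p = 0.504 with an estimated correlation). Neuronal-type genes had 1 of 8 higher, Nrgn (3 adjusted over the list alone; camera, adjusted p = 0.0324, and adjusted p = 0.25 with an estimated correlation). Of 23 immediate-early and stress genes 3 fell, Hspe1 (-1.86 ± 0.22), Jun (-0.83 ± 0.23) and Hsp90aa1 (-0.66 ± 0.21), against 6 lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.0409, and adjusted p = 0.504 with an estimated correlation). Leaving out a library ended these list calls in 3, 6, 8 and 4 of the 8 fits, with adjusted p up to 0.0934, 0.13, 0.349 and 0.566. No brush border gene rose without Chat-neg replicate 2 or 4, Nrgn did not without Chat-neg replicate 2, and 1 transcription factor rose without Chat-neg replicate 2 or 3. Jun lost its call without Chat-neg replicate 2 or 4 or Chat-pos replicate 3 or 4, and Hsp90aa1 in all fits but those without Chat-neg replicate 1 or Chat-pos replicate 1. Glycolysis genes had 1 of 17 higher, Gapdh (1 adjusted over the list alone; camera, adjusted p = 0.32), a call lost without Chat-neg replicate 1, 2 or 4 or Chat-pos replicate 4. Among Notch pathway genes 0 of 7 and among unfolded protein response genes 0 of 20 passed with edgeR, also adjusted over the list alone (camera, adjusted p = 0.32 and 0.522), and voltage-gated channel genes had 0 of 11 over all genes and 1 adjusted over the list alone (camera, adjusted p = 0.215). No acetylcholine receptor gene passed the expression filter.

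Markers of other cells were present in both gates at levels that varied between libraries. Their share of gene counts did not pass between the gates for goblet (exact permutation p = 0.2), T cell (0.0857) or enterocyte markers (0.743). Paneth cell transcripts took 5.95% and 3.44% of gene counts in Chat-pos replicates 2 and 3, 0.0609% and 0.0487% in Chat-pos replicates 1 and 4, and between 0.0789% and 0.388% in Chat-neg (exact permutation p = 0.429). None of 12 Paneth genes passed edgeR, and 0 did when adjusted over the list alone. Defa24 stood at 968 ± 779.8 CPM in Chat-neg and 12494 ± 15498 CPM in Chat-pos. Camera placed the Paneth list higher (adjusted p = 0.00318, and adjusted p = 0.47 with an estimated correlation) and, with both rich libraries left out, lower (adjusted p = 0.0196). It no longer passed without Chat-pos replicate 2 (0.0838) or 3 (0.0704). Goblet cell markers had 2 of 11 lower, Clca1 and Klk1 (3 adjusted over the list alone; camera, adjusted p = 0.0246, and adjusted p = 0.397 with an estimated correlation). Their most abundant members did not pass, Zg16 at 872 ± 1226 CPM in Chat-neg and 150.5 ± 79.9 CPM in Chat-pos and Tff3 at 801 ± 818.5 and 204 ± 74.5 CPM. Without Chat-neg replicate 4, Chat-pos replicate 1 or Chat-pos replicate 4 the goblet list no longer passed (adjusted p up to 0.0924). T cell and intraepithelial lymphocyte markers had 0 of 7 passing with edgeR, also adjusted over the list alone, and were lower as a list (camera, adjusted p = 0.0324, and adjusted p = 0.429 with an estimated correlation), with Gzma at 186 ± 49.4 CPM in Chat-neg and 52.5 ± 98.5 CPM in Chat-pos. That call was lost without Chat-neg replicate 3 or Chat-pos replicate 1, 3 or 4 (adjusted p up to 0.0843). Without Chat-pos replicate 2, the sole Chat-pos library with these transcripts at the Chat-neg level, 6 of the 7 members were lower (camera, adjusted p = 8.39e-21), with Gzma at -5.76 and Ccl5 at -4.05 on the log2 scale. With both Paneth-rich libraries left out, 5 were lower (adjusted p = 4.25e-18). Of 27 enterocyte markers 0 passed with edgeR, also adjusted over the list alone (camera, adjusted p = 0.925, and 0.0308 without Chat-neg replicate 4), with Fabp1 at 29027 ± 10474 CPM in Chat-neg and 37091 ± 12627 CPM in Chat-pos. The enteroendocrine list had 3 measured members, with Sct higher in Chat-pos (0.85 ± 0.22, lost without Chat-neg replicate 2 or Chat-pos replicate 1) and Cpe at -0.35 ± 0.74. The plasma cell and the myeloid and mast cell lists had 1 member each, Sdc1 (-0.91 ± 0.53) and Kit (0.60 ± 0.31), which did not pass, and the stromal list had none.

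**Figure D3:**
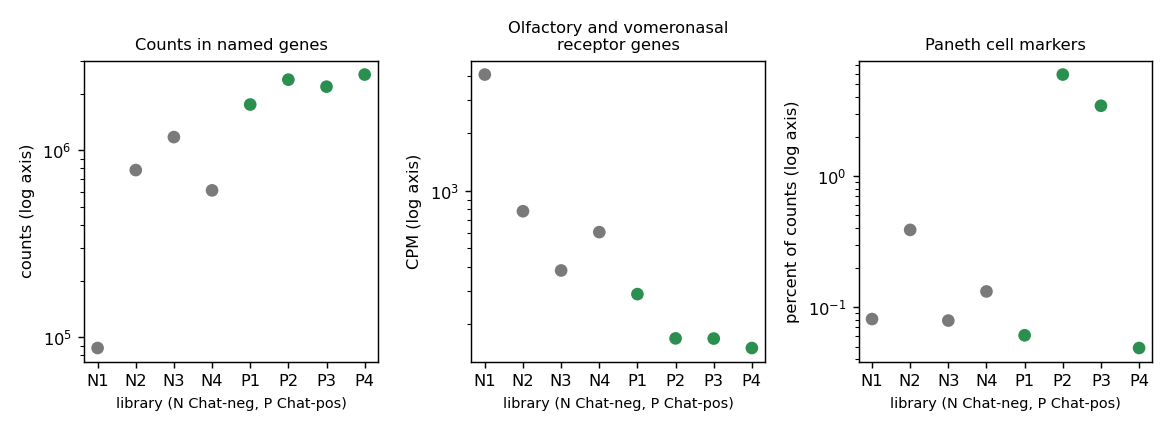
Counts in named genes, CPM of 1430 olfactory and vomeronasal receptor genes, and percent of gene counts in Paneth cell markers for each library (log axes). Chat-neg replicate 1 has the fewest counts, 87642, and Chat-pos replicates 2 and 3 hold 5.95% and 3.44% Paneth cell transcripts.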

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

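Values are listed here where a library lies far from the other 3 of its group, and the tests on Paneth cell material and on the share of tuft cells were chosen only after the results were seen. Of 252 groups of 4 values examined, 30 held such a library, where chance gives about 12.6 if values are independent and normally distributed. Some values rest on few reads, and the background entered both in CPM and per kb, so the excess over that number decides nothing. Of the 30, 9 concerned Chat-neg replicate 1, the shallowest.

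In Chat-neg replicate 1 background receptor reads reached 4073 CPM (0.768 per kb and 1e6 counts), Vapb 46.5 CPM and Nradd 23.3 CPM, above the other Chat-neg libraries. In the same library Pla2g16 was at 128 CPM, Tslp at 23.3 CPM, Atp5k at 1105 CPM, Ldha at 617 CPM and Kit at 0 CPM, below the others. Chat-neg replicate 2 stood high for Paneth cell transcripts (0.388%) and Defa30 (695.6 CPM), Chat-neg replicate 3 for Clca1 (128 CPM) and Zg16 (2706 CPM), and Chat-neg replicate 4 for Fgfbp1 (48.1 CPM) and Calhm3 (1.6 CPM, where the other 3 had 0). In Chat-pos replicate 1 the background was 287 CPM (0.0542 per kb and 1e6 counts) over 295 receptor genes, Gm10800 took 0.523% of gene counts, H2-K1 was at 3822 CPM and Hmgcs1 at 1023 CPM, all high, and Edn2 was low at 1.24 CPM. Chat-pos replicate 2 was high for T cell markers (0.0463%), Gzma (200.3 CPM), Ccl5 (147 CPM) and Gbp8 (49.3 CPM). Chat-pos replicate 3 was high for Nradd (25.0 CPM) and Pdia6 (60.5 CPM) and low for Clca1 (1.89 CPM), and Chat-pos replicate 4 was low for Sema4a (159.9 CPM). In all Chat-neg libraries the share of Gm10800 was higher than in any Chat-pos library, at 8.11%, 2.38%, 0.771% and 1.19% against 0.171% to 0.523% (exact permutation p = 0.0286, adjusted p = 0.0536 over 15 library measures). Outside the comparison, rows without a gene name held a mean of 75.5% of counts in Chat-neg and 62.3% in Chat-pos.

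Cells of other types in a gate are a candidate source of part of the difference between Chat-pos and Chat-neg, although the CD45, EPCAM and Il25-RFP gates of the sort were meant to remove them. Of 579 called genes 3, or 0.518%, are markers of another cell type, but 3 marker lists passed camera, so the planned test leaves this open; the marker lists hold 11 goblet, 12 Paneth and 7 T cell genes that passed the expression filter here. Without Chat-pos replicates 2 and 3, which hold the Paneth cell material, 212 of the 323 genes called higher pass again. Of the other 111, 98.2% keep a log2 difference over 2 standard errors above 0 there. The median of the 111 was 0.88 against 0.85 before, with a median standard error of 0.30 against 0.24. The genes were chosen in a fit that held the same remaining libraries, so the retest is not independent. It shows only that most of them also stood higher in the Chat-pos libraries poor in Paneth cell transcripts. Of the 256 genes called lower, 64 pass again in that fit, where fewer libraries also cost power. However, 173 of the 256, those with at least 10 CPM, non-overlapping groups and no predicted-model name, were lower in every Chat-pos library than in any Chat-neg library. That includes the Chat-pos libraries poor in Paneth cell transcripts. For these genes, chosen in the same data, it argues against Paneth cell material as the whole source. For the other lower genes Paneth cell material stays open. A smaller share of tuft cells in the Chat-neg gate would lower all tuft-specific genes alike. The fold changes of the tuft identity list differ among themselves with a chi-square of 6.33 per degree of freedom over their standard errors. However, the list also holds genes such as Espn, which stands in the brush border list too and need not be tuft-specific. A mix of such genes would spread the fold changes as well, so the test cannot decide on a smaller share. A difference between tuft cells with and without reporter activity stays open.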

How the results depend on the processing

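Of the alternatives, 5 were chosen after the data were seen: thinning without the shallowest library, leaving out both Paneth-rich Chat-pos libraries, background subtraction from all or from Chat-neg libraries, and the length and GC offset. Over all alternatives the 111 named genes kept direction and side of the threshold in 2107 cases, weakened in 281, strengthened in 39 and reversed in 17, and of 74 named genes that passed, 34 passed in all 8 fits that left out a library. For lists the numbers were 570, 94, 14 and 19.

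The 323 higher and 256 lower genes became 0 and 0 when thinned to the smallest library (edgeR; 77 genes at an unadjusted p under 0.05, with 1305 genes left to test), 35 and 25 with a minimum fold of 1.5, and 134 and 131 when thinned to the second smallest library without the shallowest (130 and 104 of them shared). Without a filter 143 genes were lower (344 higher), with limma-voom 402 lower, and with both Paneth-rich libraries left out 86 lower and 240 higher; the cause of these shifts was not tested. Leaving out 1 library gave 138 to 360 higher and 110 to 309 lower genes. RLE scaling gave 369 and 245, upper-quartile 328 and 303, DESeq2 397 and 239, background subtraction 476 and 212, subtraction from Chat-neg alone 465 and 212, and the length and GC offset 353 and 309. No filter moved the median of all genes to 0.18.

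The deviations gave no sign that equal replicate numbers pair: 0 of 4 same-number pairs correlated above 0.1 (-0.02 to 0.05). Of 8 libraries 3 correlated best with their own number. Shared animals are not excluded, since counting noise in shallow libraries can hide such a correlation. With the number as a block 290 genes were higher and 230 lower, and the enterocyte list turned upward (adjusted p = 0.889).

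With an estimated correlation the adjusted p was 0.298 for tuft identity, 0.214 for the taste-type cascade, 0.214 for type 2 genes, 0.429 for proliferation, 0.397 for the villus-top list and 0.232 for ribosomal proteins. Fry gave 0.207 for proliferation, 0.0673 for the villus-top list and 0.0199 for exocytosis. It also did not pass oxidative phosphorylation (0.111), brush border genes (0.13) or immediate-early and stress genes (0.274). The same held for goblet (0.111), Paneth (0.264) and T cell markers (0.129). Over fits without 1 library the adjusted p ran from 0.0326 to 0.209 for eicosanoid synthesis, from 2.66e-08 to 0.0815 for proliferation and from 0.029 to 0.776 for stem and progenitor genes. Without Paneth-rich libraries eicosanoid synthesis (0.0162), stem and progenitor genes (0.00356) and chloride and bicarbonate transport (0.0384) passed, and the Paneth list reversed to lower (0.0196), with Defa24 at -1.57 and Defa30 at -1.88; here fewer samples and the removal of those transcripts are the construction. Without a filter eicosanoid synthesis passed (0.000228), and exocytosis (0.583), voltage-gated channels (0.000549), the unfolded protein response (0.0705) and enterocyte markers (0.00461) changed direction. Enterocyte markers also did so with total count scaling (0.972), at equal depth without the shallowest library (0.864) and in 5 of 8 fits without 1 library (range 0.0308 to 0.957). Distal genes did so at equal depth (0.802) and without Chat-pos replicate 4 (0.652; range 0.188 to 0.825). The cause was not tested.

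Thinned to the smallest library, where few genes and counts are left, tuft identity (0.22) and the villus-top list (0.584) no longer passed. Eicosanoid synthesis (0.532), tuft transcription factors (0.532), the unfolded protein response (0.848) and glycolysis (0.584) changed direction. Chat was at 0.47 and Ptprc at 0.37 without passing, and Epcam (-0.36), Pla2g16 (-0.12), Il17rb (-0.0427), Id2 (-0.0839), Eps8l3 (-0.47), Sema4a (-0.40), Ano7 (-1.01), Hspe1 (0.10), Fabp1 (-0.10) and Lgals4 (-0.28) changed sign. Il25 (1.12) and Ptprc (0.99) did not pass a minimum fold of 1.5, nor Il25 (1.12) at equal depth. Lgals4 also changed sign with total count scaling (-0.014), at equal depth (-0.0616) and without Chat-neg replicate 1 (-0.0115 to 0.27 over fits without 1 library). Cpe did so without Paneth-rich libraries (0.23) and without Chat-neg replicate 4 (-1.13 to 0.29). The cause was not tested.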

Other observations

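The 5 gene groups tried beyond the preset lists (mitochondrial ribosomal, spliceosomal, phosphodiesterase, lysosomal and selenium genes, of which the lysosomal result is left out) and the tests on equal depth, length and GC trend, immature cells and background were chosen only after the results were seen. Of 77 mitochondrial ribosomal protein genes 10 fell and 0 rose with edgeR, among them Mrpl13 (-1.27 ± 0.26), Mrpl37 (-1.54 ± 0.34) and Mrps28 (-1.53 ± 0.37). Of 21 spliceosomal Sm and Lsm protein genes 6 fell, including Snrpg (-1.17 ± 0.24) and Snrpd1 (-1.12 ± 0.26). With both Paneth-rich Chat-pos libraries left out, 4 mitochondrial ribosomal and 2 spliceosomal genes fell. Without Chat-neg replicate 4 the counts were 5 and 0, and without Chat-pos replicate 3 they were 7 and 3.

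Of 7 measured cyclic nucleotide phosphodiesterase genes 3 rose, Pde4d (1.14 ± 0.23), Pde9a (1.02 ± 0.21) and Pde8b (1.17 ± 0.30); 2 did without Chat-neg replicate 2 and with both Paneth-rich libraries left out. Among 17 genes of selenoproteins and selenium handling, Selenow (1.39 ± 0.23), Selenop (1.35 ± 0.25) and Selenok (0.86 ± 0.20) rose, whereas Gpx1 (-1.07 ± 0.23) and Sephs2 (-0.82 ± 0.23) fell. With both Paneth-rich libraries left out 3 rose and 0 fell, and 1 fell without Chat-neg replicate 2 or 3 or Chat-pos replicate 2, 3 or 4. For the phosphodiesterase genes camera gave an adjusted p = 0.00238 (0.165 with an estimated correlation) and fry 0.00585. For the selenium genes camera gave an adjusted p = 0.283 (0.487 with an estimated correlation) and fry 0.234.

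The fall of ribosomal protein genes in Chat-pos may have technical or biological sources. With a trend in annotated exon length and GC content removed, the median was -1.01 on the log2 scale and 62 genes fell. These genes are short (median exon length 1806 against 4491 bp in other genes). That length joins all annotated exons of a gene, 3598 bp for Rpl12, and can exceed the transcript that is made. A bias by the length of the transcript itself is therefore not excluded. More immature or cycling tuft cells in the Chat-neg gate cannot be told apart from other causes: the proliferation list had a median of -0.96, but fry gave it an adjusted p = 0.207. Reads shared with pseudogenes were not tested.

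Unequal depth and background reads could also make differences. Thinned to the shallowest library, 0 of the 579 called genes passed edgeR, a test that cannot tell depth from lost power, with 77 of 1305 genes at an unadjusted p under 0.05. At the depth of the second smallest library, without the shallowest, the log2 fold changes of 541 called genes had a median ratio of 0.965 to those of the deposited counts and 234 of these genes passed again. Thinning keeps the expected share of each gene, so this ratio excludes nothing and depth stays confounded with the groups. After subtraction of background reads 82.8% of the genes called lower stayed called (212 of 256), from all libraries or from Chat-neg alone. The subtraction was rounded to whole reads and took none from a gene at their median exon length of 3135 bp. Most of these calls were therefore bound to stay, and the share decides little. Genes called higher had the same median length, against 4557 bp in genes not called, so the median annotated length does not separate the directions. Equal medians do not show that the lengths are spread alike. For Ttn, with 116825 bp of exons, background cannot be told apart from a true difference: the subtraction took its mean count from 17 to 7.5 in Chat-neg and from 6.75 to 0 in Chat-pos, below the expression filter, and kept in the fit its log2 difference was -1.77 ± 0.72 with Chat-neg alone subtracted and -7.00 ± 1.35 with both groups subtracted, against -3.16 ± 0.54 before. Counts this near 0 decide nothing.

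Chance as the source of the count of called genes is argued against but not excluded. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many, the real one with 579 genes. The highest of the others gave 7. This is the smallest share that 35 splits allow, and the other splits mix both gates, which raises the spread within their groups. Depth separates along the real split too, so the count does not tell the source of the difference.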
